A study of Mus musculus with 9 samples.

How the data were processed

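RNA was measured in mouse kidney by sequencing libraries made from poly(A)-selected RNA, with 3 groups of 3 libraries named in the labels: sham, bIRI, and BHB plus bIRI. Per the labels, total RNA was taken up in TRIzol, messenger RNA was captured with oligo(dT), and paired-end reads came from NovaSeq or MGISEQ instruments. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2, counted with featureCounts of the Subread package, and compared with DESeq2. The versions of these tools, the gene annotation and the strand setting were not given in the sources used here. The deposited values were raw read counts per gene, 1 count table for each library, and all 9 tables held whole numbers.

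Gene symbols, types and positions came from GENCODE mouse release M21, on GRCm38, the assembly also called mm10, which named 29220 of the gene identifiers and left 458 without a symbol. All 9 libraries held 0 counts for 633 genes. Transcript length and GC content were those of the longest protein-coding transcript of a gene, or the longest transcript of a gene without one, and were available for 17928 of 17967 genes tested (99.78%).

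The values of bIRI replicate 2 were equal, in every gene, to the mean of bIRI replicates 1 and 3 rounded down. In the other sets of 3 columns, of 252 compared, at most 2.16% of the genes with a summed count of at least 60 were equal to such a mean within 0.5 counts. This library was left out, because a mean of other libraries adds no measurement and makes the spread of the group look smaller, and the 8 others were fitted. The design, which had named all 9 libraries before the data were examined, was otherwise followed as written, and the fit of all 9 was kept as an alternative.

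Genes with low counts were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 17967 genes. Counts were scaled by TMM factors, from 0.830 for BHB plus bIRI replicate 3 to 1.37 for bIRI replicate 3. A quasi-likelihood negative binomial model with robust dispersion and 1 mean per group was fitted to the 8 libraries, with 5 residual degrees of freedom and a biological coefficient of variation of 0.296. The 3 comparisons were contrasts of this fit, and all tests were two-sided. P-values were adjusted over the genes tested by the method of Benjamini and Hochberg, within each comparison, and an adjusted p of 0.05 was the threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM values were taken from the TMM-scaled library sizes, with 0.5 CPM added before the log2 values of gene lists and a prior count of 2 for principal components.

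Gene lists for nephron segments, fuel metabolism, mitochondria, injury, inflammation, immune cells and related processes were written before the data were examined, and 49 of them had at least 3 genes tested. They were tested with camera of limma 3.58.1 on voom weights, with its preset correlation of 0.01 and again with a correlation estimated from the data, and with fry. Adjustment ran over the 49 lists within each comparison, while the nuclear OXPHOS list was named as a result of its own and is given with unadjusted p. The list of cytosolic ribosomal proteins was made after the data had been seen.

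Genes for the text were drawn from those that a rule selected before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls past the threshold, among genes whose groups did not overlap in CPM and whose mean was at least 5 CPM in a group, with predicted gene models left out. It added up to 4 called members of each list, and a fixed set of genes of tubular injury, ketone metabolism, BHB signalling and inflammation. Neat1, Malat1, Srrm2, Ighm, Igkc and Jchain were named after their values had been seen. For a gene with no counts in a group, folds were computed against a floor of 3 counts per library. Confidence intervals at 95% for shares and ratios of counts were exact binomial or Poisson intervals.

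Before the data were examined, these alternatives were set: DESeq2 1.42.0, RLE and upper-quartile factors, scaling without mitochondrially encoded genes and the 20 most abundant genes, no filter and a filter at 1 CPM in 3 libraries, a fit of the compared groups only, the replicate number as a block, a fold change of at least 2, and leaving out each library. DESeq2 was run on the 8 libraries. After the data had been seen, the fit of all 9 tables was added, as was a correction for GC content and transcript length. That correction fitted each library's deviation from the mean log2 CPM by natural splines with 5 degrees of freedom in each property, over genes with a mean log2 CPM above 1, and used the fitted trends as offsets. For matched lists, 10000 random lists of genes similar in length, GC content and expression were drawn.

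The procedure was tested on simulated data, with counts drawn from the mean CPM of each of 17967 genes over the 8 libraries. Each gene had 1 dispersion, the same in all groups, and 200 genes were changed in each comparison. Of genes changed 4-fold, 61.2% to 65.3% were called, of genes changed 2-fold 10.1% to 14.3%, and 3 to 5 unchanged genes were called. Further simulations, 20 without any effect, gave the correlation between comparisons that share libraries. In the data the median SD of log2 CPM was 0.363 in bIRI, 0.161 in sham and 0.200 in BHB plus bIRI. The simulations did not copy this larger spread in bIRI, so their rates may differ from those of comparisons with bIRI. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the tables and plots.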

Results

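Gene expression was measured by RNA-seq of poly(A)-selected RNA from mouse kidney in 3 groups, 24 h after reperfusion. The groups were sham-operated kidneys (sham), kidneys after bilateral ischemia-reperfusion injury (bIRI), and kidneys with the same injury after pretreatment with the sodium salt of beta-hydroxybutyrate (BHB plus bIRI), a ketone body that tissues burn as fuel in fasting. The labels list 3 libraries per group and give neither the dose and timing of BHB nor the age, sex or number of mice. The values deposited for bIRI replicate 2 equalled the mean of bIRI replicates 1 and 3, rounded down, in every gene, so that 8 libraries were compared, with 2 of bIRI. Total counts were 43206974, 45909063 and 43498290 for sham replicates 1, 2 and 3, 41204065 and 33477985 for bIRI replicates 1 and 3, and 44225882, 45014455 and 44376140 for BHB plus bIRI replicates 1, 2 and 3. A floor of 3 counts corresponded to a counts-per-million (CPM) value of 0.0646 to 0.0815 on the library sizes scaled by trimmed means of M-values (TMM), and intervals and floors here cover counting error only. The p-values measure only the spread between the libraries of a group, since no label says that each library came from its own animal.

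The 3 groups separated on the first principal component of log2 CPM, which held 57.4% of the variance. The second component, with 22.7%, was set mainly by bIRI replicate 3, at -130.2, while bIRI replicate 1 lay at -5.92. The root mean square log2 difference over genes was 1.17 between both bIRI libraries and 0.730 between bIRI replicate 1 and BHB plus bIRI replicate 2. Long intergenic RNA genes held 0.573% of counts in bIRI replicate 3 and 0.140% to 0.179% in the other 7 libraries. Mitochondrially encoded genes held 11.2% to 13.3% of counts in sham, 15.9% in both bIRI libraries and 24.0% to 30.3% in BHB plus bIRI.

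**Figure D1:**
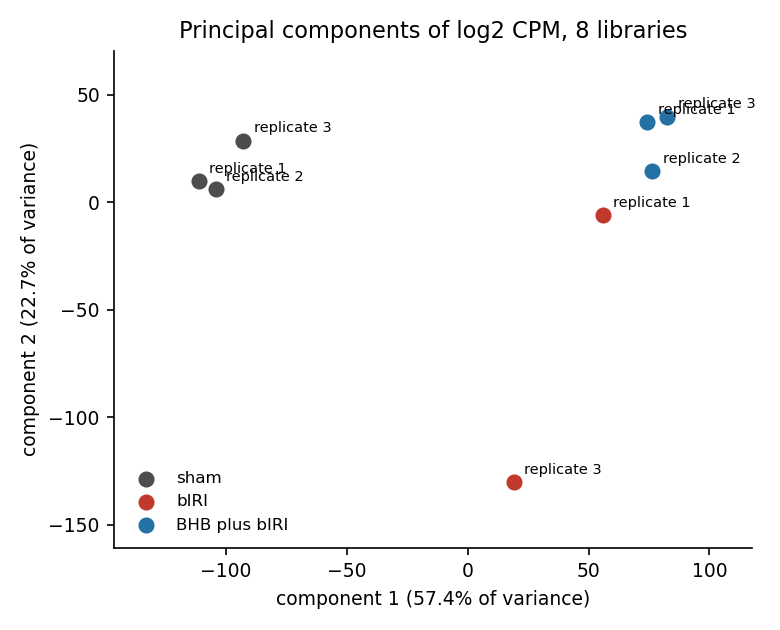
Principal components 1 and 2 of log2 CPM for the 8 libraries, with each point a library and each colour a group. Component 1 held 57.4% and component 2 held 22.7% of the variance, and bIRI replicate 3 lay at -130.2 on component 2.

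The first comparison, bIRI against sham, asked what ischemia and reperfusion did to kidney gene expression. Markers of injured tubules rose steeply and the transporters and enzymes of the proximal tubule fell. Lcn2, which encodes the secreted iron-carrier-binding protein NGAL (ENSMUSG00000026822, GRCm38/mm10 chromosome 2, 32384633 to 32388252), rose 633-fold, from 2.71 ± 0.703 CPM (SD, n = 3) in sham to 2435 and 1000 CPM in bIRI replicates 1 and 3. Havcr1, the gene of the phagocytic receptor KIM-1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), rose 385-fold to 1929 and 534 CPM. Slc34a1, the main phosphate transporter of the proximal tubule (ENSMUSG00000021490, chromosome 13, 55398187 to 55415592), fell from 4952 ± 490 CPM (SD, n = 3) in sham to 535 and 359 CPM in bIRI.

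By edgeR, 6303 of 17967 genes tested passed an adjusted p of 0.05, with 3396 higher and 2907 lower in bIRI. Values of both groups did not overlap for 55.9% of the genes tested, where chance gives 20%. Of the 24 tubular injury markers, 21 rose and 3 were not called, and 22 were higher when adjusted over the list alone. Their median log2 fold change was 2.82, and limma camera gave an adjusted p of 8.3e-13 with its preset correlation and an adjusted p = 0.209 with an estimated correlation. Spp1, the gene of osteopontin, rose by 5.34 on the log2 scale (SE 0.30), the chaperone gene Clu by 2.82 (SE 0.25), and the epithelial keratin gene Krt20 by 10.44 (SE 1.17), with 719 and 41.9 CPM in bIRI replicates 1 and 3. Among the largest rises, Sprr2f, a gene of the cornified envelope family that shares sequence with its near copies and is therefore uncertain, was at least 429-fold higher than the floor of 3 counts per library, since sham libraries held no counts. Grp, a gastrin-releasing peptide gene, was likewise at least 73.7-fold higher, and Vgf, a secreted neuropeptide precursor gene with 1 count in sham, was higher by a ratio of 1736 (95% counting interval 311 to 68637). Crct1 was at least 71.3-fold higher, at 10.4 CPM in bIRI replicate 1 and 0.0436 CPM in bIRI replicate 3.

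Proximal tubule genes fell as a group. Of the 18 genes of segments S1 and S2, 17 fell, with a mean log2 fold change of -2.72 (SD over genes 1.06) and a camera adjusted p of 3.81e-12, or an adjusted p = 0.0645 with an estimated correlation. The inositol-degrading enzyme gene Miox fell by 4.23 on the log2 scale, and the endocytic receptor gene Lrp2 fell as well. Of the 12 genes of segment S3, 9 fell, among them the amino acid transporter gene Slc7a13, which fell by 3.36 (list adjusted p 2.64e-07 by camera, and adjusted p = 0.142 with an estimated correlation). Amino acid catabolism of the proximal tubule fell in 18 of 21 genes, including the creatine pathway gene Gatm, which fell by 4.81. It was the list that limma camera called both with the preset correlation (adjusted p 4.14e-14) and with an estimated correlation (adjusted p = 0.0152). Igfbp1, an insulin-like growth factor binding protein gene, and Fam151a were among the genes with the largest falls, with log2 fold changes of -4.83 (SE 0.42) and -5.17 (SE 0.44).

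Genes of fatty acid oxidation, the tricarboxylic acid cycle, gluconeogenesis and ketone body metabolism were lower in bIRI, and glycolysis genes moved both ways. Of 26 fatty acid oxidation genes, 24 fell and 0 rose, with a mean log2 fold change of -1.58 (SD over genes 0.516; camera adjusted p 3.76e-13, and adjusted p = 0.17 with an estimated correlation). Cpt1a, which encodes the enzyme that admits fatty acids to mitochondria, fell by 1.15 (SE 0.24), and Ehhadh, of peroxisomal beta-oxidation, by 2.40 (SE 0.41). In the tricarboxylic acid cycle, 15 of 18 genes fell (camera adjusted p 1.14e-08, and adjusted p = 0.0777 with an estimated correlation). Of 16 glycolysis genes 5 rose and 4 fell, with a mean log2 fold change of 0.05 (SD over genes 1.44), while the camera direction was down (camera adjusted p 0.664). All 6 gluconeogenesis genes fell, with a list adjusted p of 2.88e-07 by camera and an adjusted p = 0.126 with an estimated correlation. In ketone body metabolism, 7 genes fell and 1 rose (camera adjusted p 0.000151, and adjusted p = 0.0777 with an estimated correlation). Bdh1 and Oxct1, whose enzymes make BHB usable as fuel, fell by 2.22 (SE 0.36) and 1.37 (SE 0.25), and Hcar2, a receptor of BHB on immune cells, rose by 2.31 (SE 0.68) from 0.199, 0.160 and 0.258 CPM in the sham libraries.

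Nuclear genes of oxidative phosphorylation (OXPHOS) fell in bIRI. The 79 measured genes listed for complexes I to V were mostly subunit genes, with a few partners such as the cytochrome c gene Cycs and the ATP synthase inhibitor gene Atpif1. Of these 79 genes, 43 fell and 0 rose, and 53 were lower when adjusted over the list alone. The mean log2 fold change was -0.89 (SD over genes 0.454), with a camera p of 9.16e-15, p = 0.172 with an estimated correlation, and a fry p of 0.00577. With trends in transcript length and GC content taken out, an alternative chosen after seeing the data, the mean was -0.64 and 49 genes were lower. Complex II fell in 4 of 4 genes, complex V in 12 of 16, complex I in 18 of 36, complex IV in 5 of 13 and complex III in 4 of 10. The succinate dehydrogenase gene Sdha fell by 1.54 (SE 0.21), the ATP synthase gene Atp5b by 1.57 (SE 0.24) and the complex I gene Ndufs1 by 1.46 (SE 0.21). Of the 13 mitochondrially encoded genes, 0 passed the edgeR test in either direction.

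Genes of inflammation, matrix and cell division were higher in bIRI. Inflammatory cytokines and chemokines rose in 12 genes and fell in 1 (camera adjusted p 0.00193, and adjusted p = 0.452 with an estimated correlation). Ccl2, which attracts monocytes, rose by 2.40 (SE 0.54), and Il6 had 2.47 CPM in bIRI replicate 1 and 0.0436 CPM in bIRI replicate 3. Extracellular matrix and fibrosis genes rose in 17 of 23, among them Timp1, an inhibitor of matrix proteases, by 6.12 (SE 0.61), and Tnc, the tenascin gene, by 4.26 (SE 0.63); the list had a camera adjusted p of 4.21e-06 and an adjusted p = 0.461 with an estimated correlation. Cell cycle and proliferation genes rose in 15 of 28 (camera adjusted p 1.08e-05, and adjusted p = 0.299 with an estimated correlation), with Top2a at 2.20 (SE 0.34) and Mcm3 at 1.40 (SE 0.23). Mki67, a marker gene of dividing cells, rose by 4.82 (SE 0.74), with 3.79 and 16.9 CPM in bIRI replicates 1 and 3. The cell cycle inhibitor gene Cdkn1a rose by 4.33 (SE 0.56) in a list of apoptosis and p53 targets with 12 genes higher and 1 lower (camera adjusted p 0.0026, and adjusted p = 0.461 with an estimated correlation). Neutrophil genes rose in 7 of 9 (camera adjusted p 0.0165, and adjusted p = 0.521 with an estimated correlation), while T and natural killer cell genes fell in 6 of 12 (camera adjusted p 0.00154, and adjusted p = 0.276 with an estimated correlation). Both lists had low levels. With 0.5 CPM added, mean log2 CPM of the T and natural killer cell list was 0.247 in sham and -0.670 and -0.483 in bIRI replicates 1 and 3. The neutrophil list was at -0.532 in sham. Mean log2 CPM of the matrix, apoptosis and neutrophil lists lay above sham by 2.505, 1.104 and 1.903 in bIRI replicate 1. In bIRI replicate 3 the distances were 0.985, 0.402 and 0.769. The cell cycle list lay above sham by 0.863 in bIRI replicate 1 and 1.132 in bIRI replicate 3. With the other lists of this comparison, camera called 24 of 49 fixed lists, 9 up and 15 down, and 1 of 49 with an estimated correlation. Fry called 26 of the 49, and 22 of these were shared with camera at its preset correlation. Without sham replicate 1 or 2, edgeR called 4180 and 4192 genes, against 6303 with all 8 libraries.

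**Figure D2:**
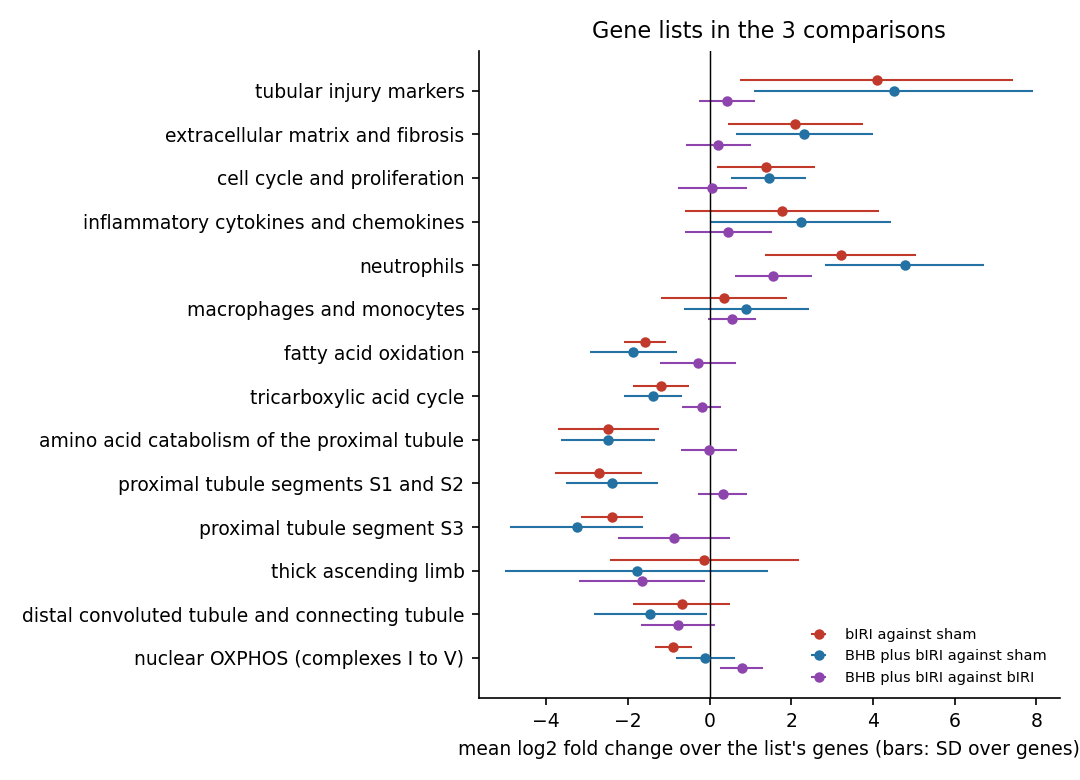
Mean log2 fold change over the genes of 14 lists in the 3 comparisons, with bars for the SD over genes. The mean for nuclear OXPHOS genes was -0.89 in bIRI against sham, 0.79 in BHB plus bIRI against bIRI and -0.11 in BHB plus bIRI against sham, and the injury marker means include 1 gene without counts in sham.

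The second comparison, BHB plus bIRI against bIRI, asked what BHB pretreatment changed in the injured kidney. With the preset correlation of camera, nuclear OXPHOS genes and neutrophil genes were called higher with BHB, and thick ascending limb and distal convoluted tubule genes lower, while none of these lists was called with an estimated correlation. In edgeR, 30 of 79, 3 of 9, 6 of 12 and 3 of 10 genes of these lists passed, and the injury marker genes Lcn2, Havcr1 and Krt20 did not. Of the 79 nuclear OXPHOS genes, 30 rose and 0 fell, with a mean log2 fold change of 0.79 (SD over genes 0.530), 53 higher and 3 lower when adjusted over the list alone, and a camera p of 1e-16, p = 0.115 with an estimated correlation. The fry test gave a p of 0.00977 for the list. Ndufa11, of complex I (ENSMUSG00000002379, chromosome 17, 56717767 to 56722141), rose 3.61-fold from 40.3 and 16.7 CPM in bIRI to 103 ± 32.0 CPM (SD, n = 3), and Atp5e, of the ATP synthase (ENSMUSG00000016252, chromosome 2, 174461072 to 174464105), rose 3.33-fold.

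By edgeR, 2431 genes passed an adjusted p of 0.05, with 876 higher and 1555 lower in BHB plus bIRI, and 6191 had an unadjusted p under 0.05. Values of both groups did not overlap for 46.01% of the genes, where chance gives 20%. Within OXPHOS, complex I rose in 17 of 36 genes (camera adjusted p 3.14e-11, and adjusted p = 0.792 with an estimated correlation) and complex V in 9 of 16 (camera adjusted p 1.37e-05, and adjusted p = 0.792 with an estimated correlation). Complexes III and IV rose in 2 of 10 and 1 of 13 genes, with camera adjusted p of 0.0094 and 0.00278 and an adjusted p = 0.792 with an estimated correlation for each. Complex II, with Sdhb higher by 0.92 (SE 0.23) and Sdha at -0.58 (SE 0.20, edgeR adjusted p 0.0739), had a camera adjusted p of 0.632. The mean nuclear OXPHOS level in log2 CPM was 7.02 in bIRI replicate 1 and 6.65 in bIRI replicate 3, 7.64 ± 0.255 (SD, n = 3) in BHB plus bIRI and 7.75 ± 0.211 (SD, n = 3) in sham.

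**Figure D3:**
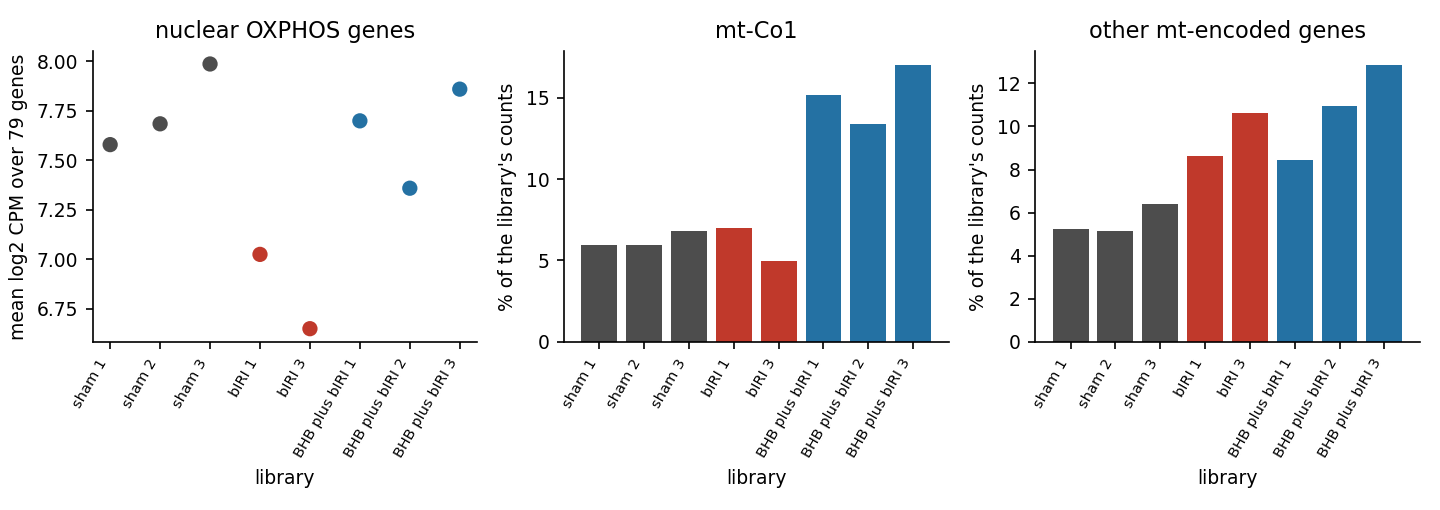
Mean log2 CPM over 79 nuclear OXPHOS genes, and the percent of counts held by mt-Co1 and by the other mitochondrially encoded protein-coding genes, in each of the 8 libraries. The OXPHOS mean was 7.02 and 6.65 in the bIRI libraries, and mt-Co1 held 13.4% to 17.0% of counts in BHB plus bIRI.

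Fold changes in this comparison followed transcript length across the genome. Over 12395 genes, Spearman's rho between the log2 fold change and transcript length was -0.537, and rho with GC content was 0.445, where genes are not independent replicates. Weaker trends were present in the other comparisons. With length and GC content, rho was 0.214 and -0.22 in bIRI against sham, and -0.185 and 0.095 in BHB plus bIRI against sham. Nuclear OXPHOS transcripts were short, with a median of 908 bases against 2761 for the genes tested. After smooth trends in length and GC content were taken out of each library, an alternative chosen after seeing the data, the OXPHOS mean was 0.16. EdgeR called 0 of the 79 genes. The camera p was 0.00194 with the preset correlation, and an estimated correlation was not run on the corrected values. Genes for cytosolic ribosomal proteins, a list made after seeing the data, rose in 48 of 80, with a mean log2 fold change of 1.22 (SD over genes 0.427). Rps27a, the ribosomal protein and ubiquitin fusion gene, rose by 2.52 (SE 0.48). The mitochondrially encoded genes mt-Co1 and mt-Co3 rose, and 11 of 13 were not called (camera adjusted p 0.0349, and adjusted p = 0.792 with an estimated correlation). Cytochrome oxidase subunit gene mt-Co1 (ENSMUSG00000064351, chromosome M, 5328 to 6872) rose 3.30-fold, and reads shared with nuclear copies were not examined for either gene. The mitochondrially encoded protein-coding genes other than mt-Co1 held 8.44% to 12.9% of counts in BHB plus bIRI and 8.65% and 10.6% in bIRI.

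**Figure D4:**
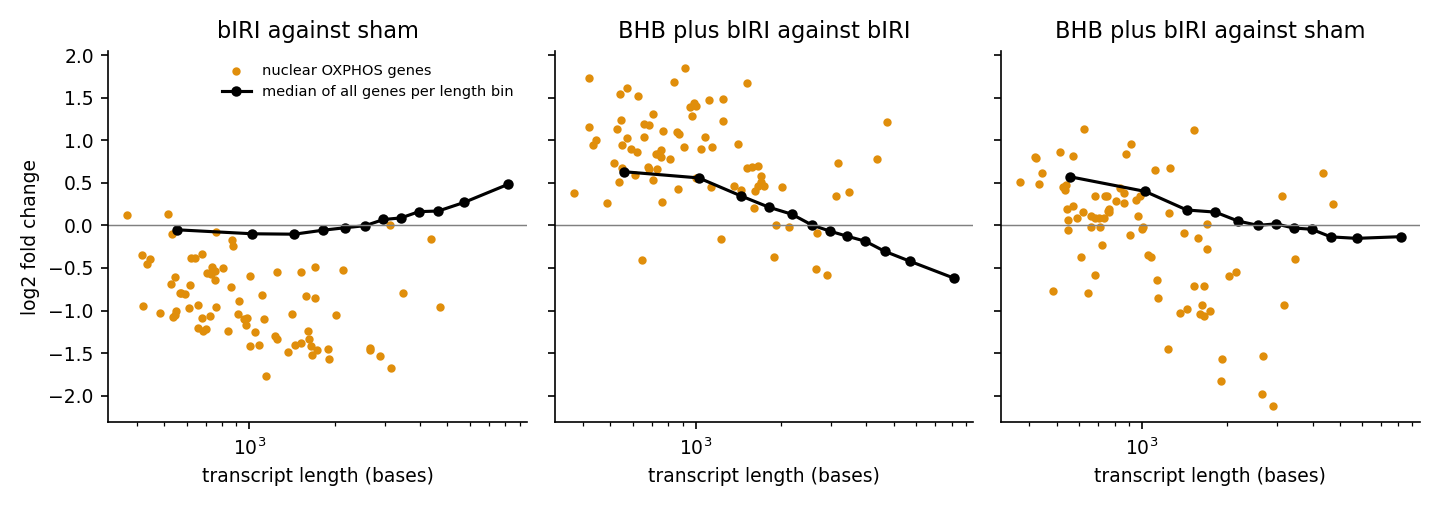
Log2 fold change against transcript length in bases (log axis) for the nuclear OXPHOS genes, with the median of all genes in 12 bins of length, in the 3 comparisons. In BHB plus bIRI against bIRI the median ran from 0.63 in the shortest bin to -0.62 in the longest.

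The main markers of tubular injury were not called with BHB. Lcn2 and Havcr1 had log2 fold changes of -0.07 (SE 0.37, edgeR adjusted p 0.913) and -0.03 (SE 0.53, adjusted p 0.972), and Krt20 and Spp1 of -0.71 (SE 0.81) and -0.73 (SE 0.26, adjusted p 0.0878). Of the 24 injury markers, 2 rose and 0 fell, the simple-epithelium keratin genes Krt18, by 1.31 (SE 0.27), and Krt19, by 1.21 (SE 0.30). The list had a camera adjusted p of 0.018 upward and an adjusted p = 0.801 with an estimated correlation, and its mean level was 7.82 in bIRI replicate 1, 6.66 in bIRI replicate 3 and 7.83 in BHB plus bIRI, in log2 CPM. With bIRI replicate 3 as the lone bIRI library, Lcn2 was higher with BHB by 0.77 and Krt20 by 2.53, where 1 library gives no spread for its group. With bIRI replicate 1 as the lone bIRI library, they were at -0.58 and -1.63.

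Neutrophil genes rose with BHB in 3 of 9, with a camera adjusted p of 0.00278 and an adjusted p = 0.792 with an estimated correlation. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, rose by 3.01 (SE 0.61) and 2.57 (SE 0.61), and Csf3r, the receptor gene for granulocyte colony-stimulating factor, by 2.51 (SE 0.48). S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035) was at 2.95 and 0.611 CPM in bIRI and 14.4 ± 3.81 CPM (SD, n = 3) with BHB. Among macrophage and monocyte genes, the Fc receptor gene Fcgr1 rose by 1.54 (SE 0.33) and 15 of 16 were not called (camera adjusted p 0.0361, and adjusted p = 0.792 with an estimated correlation). The chemokine gene Ccl7 rose by 2.87 (SE 0.57) and Nfkb2, of the non-canonical NF-kappa-B pathway, by 1.34 (SE 0.23), in a cytokine list with 4 genes higher and 1 lower (camera adjusted p 0.0995).

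Part of the genes of the thick ascending limb and the distal convoluted tubule were lower with BHB. Of the 12 thick ascending limb genes, 6 fell and 0 rose (camera adjusted p 0.0361, and adjusted p = 0.801 with an estimated correlation). Slc12a1, the sodium-potassium-chloride transporter gene (ENSMUSG00000027202, chromosome 2, 125152505 to 125230002), fell by 4.74 (SE 1.02), with 33.1 CPM in bIRI replicate 1, 1114 CPM in bIRI replicate 3 and 21.5 ± 3.74 CPM (SD, n = 3) with BHB. Egf and Umod, which encode secreted proteins of this segment, fell by 2.93 (SE 0.59) and 1.98 (SE 0.51). The mean level of the list was 4.87 in bIRI replicate 1, 6.69 in bIRI replicate 3 and 4.57 ± 0.470 (SD, n = 3) with BHB, in log2 CPM. Sham was at 6.595 ± 0.248 (SD, n = 3), near bIRI replicate 3. The BHB mean lay at -0.30 from bIRI replicate 1 and at -2.12 from bIRI replicate 3. Distal convoluted and connecting tubule genes fell in 3 of 10, Calb1, Slc8a1 and Wnk1 (camera adjusted p 0.0418, and adjusted p = 0.792 with an estimated correlation), and the BHB mean lay at -0.38 from bIRI replicate 1 and at -0.92 from bIRI replicate 3. Collecting duct lists were not called: of 9 principal cell genes 1 rose and 0 fell (camera adjusted p 0.572), and of 10 intercalated cell genes 0 rose and 1 fell (camera adjusted p 0.17), and both mean levels with BHB were above bIRI replicate 1, by 0.25 and 0.22, and differed from bIRI replicate 3 by -0.73 and -1.17. Calb1, the calcium buffer gene calbindin (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064), was nearly equal in both bIRI libraries, at 143 and 142 CPM, and fell by 2.09 (SE 0.22) to 33.5 ± 9.06 CPM (SD, n = 3) with BHB. Other genes that fell were Acadvl, of long-chain fatty acid oxidation, by 1.98 (SE 0.26), Dld, a subunit gene of the pyruvate dehydrogenase complex, by 0.98 (SE 0.18), and Gclc, of glutathione synthesis, by 1.04 (SE 0.20).

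Lists of fatty acid oxidation, glycolysis, the tricarboxylic acid cycle and ketone body metabolism were not called by camera. Of 16 glycolysis genes 1 rose and 1 fell (camera adjusted p 0.808). In fatty acid oxidation 7 genes fell, with Cpt1a by 0.91 (SE 0.23), and 1 rose, the electron transfer flavoprotein gene Etfb, by 2.33 (SE 0.54); the list had a camera adjusted p of 0.261. In the tricarboxylic acid cycle 4 of 18 genes fell and 0 rose (camera adjusted p 0.331). Of the ketone body genes 1 fell and 0 rose (camera adjusted p 0.594), and Bdh1 and Oxct1 had log2 fold changes of -0.55 (SE 0.33) and -0.50 (SE 0.23), with edgeR adjusted p of 0.263 and 0.16. Ppargc1a, a regulator of mitochondrial gene expression, fell by 1.92 (SE 0.45), with 18.4 and 79.3 CPM in bIRI replicates 1 and 3. Of the 18 genes of proximal tubule segments S1 and S2, 0 passed the edgeR test, and Slc34a1 was at 0.55 (SE 0.26, adjusted p 0.171). Of the 12 segment S3 genes 1 rose and 3 fell, with a mean log2 fold change of -0.87 (SD over genes 1.37, camera adjusted p 0.139). The BHB mean of the S3 list lay at -0.27 from bIRI replicate 1 and at -1.06 from bIRI replicate 3. The 10 largest falls of the genes that met the rule for naming were all in genes higher in bIRI replicate 3 than in replicate 1, such as Abca13, at 6.39 and 54.8 CPM in bIRI and 0.614 CPM with BHB.

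Genes tied to the signalling roles of BHB and to cell death were followed as well. The list of genes around histone deacetylases and Foxo3 had 0 genes higher and 1 lower of 14 with BHB (camera adjusted p 0.242), and Foxo3 itself was at -0.61 (SE 0.20, edgeR adjusted p 0.0711). The metallothionein genes Mt1 and Mt2 rose in bIRI against sham, by 2.57 (SE 0.60) and 4.87 (SE 0.91), and were at 0.84 (SE 0.61) and 0.39 (SE 0.75) with BHB, with edgeR adjusted p of 0.356 and 0.744. Without bIRI replicate 1, which leaves 1 bIRI library, Mt1 was at 0.69 in bIRI against sham. In that fit Mt1 was at 2.69 and Mt2 at 2.55 with BHB. Inflammasome and pyroptosis genes had 1 higher and 1 lower of 12 with BHB (camera adjusted p 0.616), with Nlrp3 at -0.37 (SE 0.57, adjusted p 0.677) and Il1b at 2.09 (SE 0.65, adjusted p 0.0587). Tnf was at 0.62 (SE 0.70, edgeR adjusted p 0.563). Among 16 ferroptosis genes 0 were higher and 3 lower (camera adjusted p 0.935). Acsl4, which feeds unsaturated fatty acids into membranes, rose by 1.93 (SE 0.23) in bIRI against sham and fell by 1.04 (SE 0.23) with BHB, while Gpx4, which protects membranes from oxidation, fell by 1.31 (SE 0.31) in bIRI and was at 1.01 (SE 0.31, edgeR adjusted p 0.0562) with BHB. The ketone enzyme gene Acat1 fell in bIRI by 1.84 (SE 0.22) and was at -0.66 (SE 0.21, edgeR adjusted p 0.0594) with BHB. Slc16a1, a transporter gene for ketone bodies, and Tfam, of mitochondrial DNA upkeep, were at 0.04 (SE 0.47, adjusted p 0.958) and -0.20 (SE 0.19, adjusted p 0.486) by edgeR.

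The number of genes called in this comparison depended strongly on single libraries and on the fit. EdgeR called 794 genes without bIRI replicate 3 and 8381 without bIRI replicate 1, and 0 without sham replicate 1, sham replicate 2 or BHB plus bIRI replicate 1, where 5566, 5307 and 4676 genes had an unadjusted p under 0.05. DESeq2, with all 8 libraries, called 4210 genes. With only the groups compared in the fit, edgeR called 1 gene, and 4495 had an unadjusted p under 0.05. After the length and GC correction, chosen after seeing the data, it called 2 genes, and 4667 had an unadjusted p under 0.05. With the replicate number as a block it called 0, with 5270, although residuals of libraries with the same number did not show a pairing (r from -0.206 to 0.0925). Of the 79 genes named in the report and the observations after it, 39 passed in this comparison with the 3-group fit, and in each of these 3 fits all 39 lost the threshold and kept their direction. Without bIRI replicate 3, 3 of the 79 nuclear OXPHOS genes passed the edgeR test, and the mean log2 fold change over all 79 was 0.64. Camera called 10 of 49 lists, 8 up and 2 down, and 0 with an estimated correlation, and fry called 0.

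**Figure D5:**
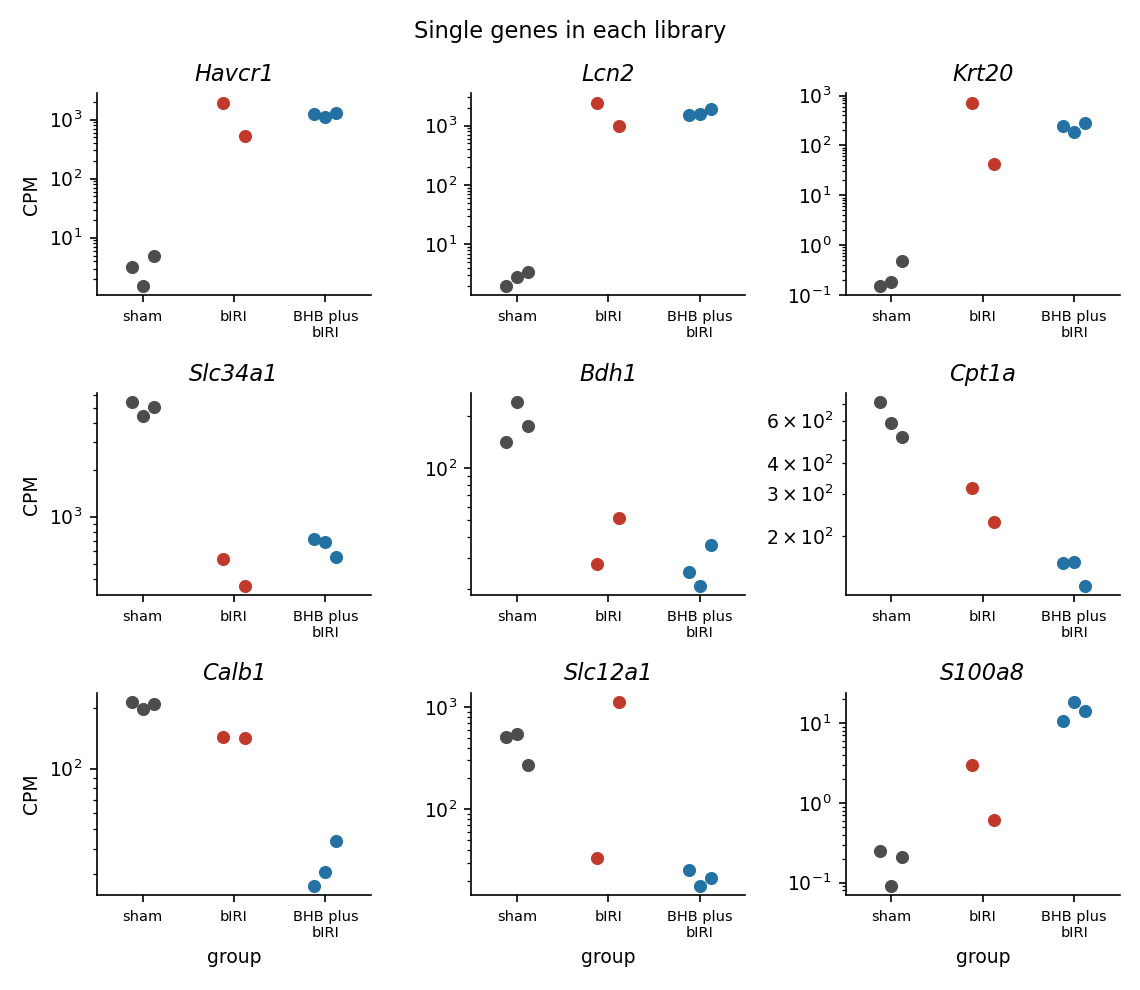
CPM on a log axis for 9 genes in each library, with a point per library. Calb1 was at 143 and 142 CPM in bIRI, and Slc12a1 at 33.1 and 1114 CPM.

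The third comparison, BHB plus bIRI against sham, asked how far pretreated injured kidneys stood from uninjured ones. Injury markers were high and proximal tubule genes low: Lcn2 was 604-fold and Havcr1 376-fold higher than in sham, and Slc34a1 fell by 2.92 (SE 0.25). Nuclear OXPHOS genes had a mean log2 fold change of -0.11 (SD over genes 0.724), with 5 higher and 20 lower, a camera p of 0.389 and p = 0.866 with an estimated correlation. The median over these genes was 0.08, of the opposite sign to the mean. Their members moved apart, with Ndufb7 and Uqcrq, of complexes I and III, higher by 1.13 (SE 0.27) and 1.12 (SE 0.35), and Sdha and Ndufs1 lower at -2.12 (SE 0.18) and -1.98 (SE 0.19). With length and GC trends taken out, chosen after seeing the data, the mean was -0.48 and 40 of 79 genes were lower. The camera p was 1.26e-07 with the preset correlation, and an estimated correlation was not run on the corrected values.

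By edgeR, 7826 genes passed an adjusted p of 0.05, with 3829 higher and 3997 lower, and groups did not overlap for 64.8% of genes, where chance gives 10%. Injury markers rose in 22 of 24 genes (median log2 fold change 3.83, camera adjusted p 3.96e-13, and adjusted p = 0.191 with an estimated correlation). Sprr2f was at least 1572-fold and Grp at least 230-fold higher than the floor of 3 counts per library. Of 16 glycolysis genes 4 rose and 4 fell (camera adjusted p 0.906). Fatty acid oxidation fell in 24 of 26 genes (camera adjusted p 1.12e-12, and adjusted p = 0.186 with an estimated correlation), with Acadvl at -3.55 (SE 0.26) and Cpt1a at -2.05 (SE 0.22). The tricarboxylic acid cycle fell in 16 of 18 genes and ketone body metabolism in 8, with camera adjusted p of 2.22e-09 and 0.000215 (adjusted p = 0.0672 and 0.083 with an estimated correlation). Bdh1 fell by 2.77 (SE 0.32). Amino acid catabolism fell in 20 of 21 genes, with a camera adjusted p of 3.96e-13 and an adjusted p = 0.019 with an estimated correlation. Thick ascending limb genes fell in 8 of 12 and rose in 1 (camera adjusted p 0.00255, and adjusted p = 0.444 with an estimated correlation), and distal convoluted and connecting tubule genes fell in 7 of 10 (camera adjusted p 0.00369, and adjusted p = 0.283 with an estimated correlation). Egf fell by 6.79 (SE 0.67), Slc12a1 by 4.35 (SE 0.97) and Calb1 by 2.63 (SE 0.21), while Abca13, a transporter gene, had the largest fall of the genes that met the rule for naming, by 7.55 (SE 0.88).

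Neutrophil genes rose in 8 of 9 (camera adjusted p 0.000499, and adjusted p = 0.359 with an estimated correlation), with S100a8 at 6.29 (SE 0.65). Extracellular matrix genes rose in 20 of 23 (camera adjusted p 5.1e-08, and adjusted p = 0.369 with an estimated correlation), with Timp1 at 7.47 (SE 0.62). Cell cycle genes rose in 20 of 28 and fell in 1 (camera adjusted p 4.32e-07, and adjusted p = 0.252 with an estimated correlation), with Mcm3 at 2.60 (SE 0.22). Mitochondrially encoded genes rose in 9 of 13 (camera adjusted p 0.00245, and adjusted p = 0.359 with an estimated correlation), with mt-Co1 at 1.28 (SE 0.33), and ribosomal protein genes rose in 69 of 80. Camera called 26 of 49 lists, 12 up and 14 down, and 1 with an estimated correlation. Fry called 32 of the 49, and 25 of these were shared with camera at its preset correlation.

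Genes changed by injury were then followed into the BHB comparison. Of the 6303 genes called in bIRI against sham, 895 were called in the opposite direction in BHB plus bIRI against bIRI and 195 in the same direction. The 895 depended on the libraries and the fit: edgeR gave 0 without sham replicate 1, sham replicate 2, BHB plus bIRI replicate 1 or BHB plus bIRI replicate 3, and 4529 without bIRI replicate 1. It gave 0 with only the groups compared in the fit and 2 after the length and GC correction, chosen after seeing the data, and DESeq2 gave 1508. Of the 3396 genes higher in bIRI, 635 were lower with BHB, where independent lists would share 294, and of the 2907 lower in bIRI, 260 were higher with BHB, where independent lists would share 142. Trp53inp1, a p53 target, and Gabpa, a regulator of mitochondrial genes, were among those higher in bIRI, at 0.83 (SE 0.17) and 0.67 (SE 0.18), and lower with BHB, at -1.10 (SE 0.17) and -1.01 (SE 0.18). Both comparisons share the bIRI libraries, which alone pulls their fold changes apart. Across genes, Pearson's r was -0.183, against a mean of -0.608 in 20 simulations without any effect, with the same dispersions in all groups. Without any effect r is set by the shared libraries, while real effects add variance, so that these values of r cannot be compared. The covariance of the edgeR fold changes was -0.267, against a mean of -0.159 in the simulations. The bIRI libraries' own difference, taken on log2 CPM rather than on edgeR fold changes, gave an expected covariance of -0.345. On log2 CPM, with bIRI replicate 1 in the first comparison and replicate 3 in the second, r was 0.202, and with the libraries exchanged it was -0.0699. Both comparisons against sham had r of 0.797 across genes, against 0.442 in the simulations with shared sham libraries, where the same limit holds. Their covariance was 1.892, against 0.102 in the simulations. They shared 2071 genes higher and 2216 genes lower, where independent lists would share 724 and 647.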

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

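The tests chosen after the results were seen are the fit of all 9 tables and the correction for GC content and transcript length. Where an arm kept 1 library, that library was assumed to vary like the other groups, and unless stated the cause of a change was not tested.

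In BHB plus bIRI against bIRI, edgeR called 2431 genes with the 8 libraries. It called 1568 with a fold change of at least 2, which is a stricter criterion by construction, 5847 with all 9 tables, which add a library made from the others, and DESeq2 called 4210. Fitted to the compared groups only, edgeR called 1, with 4495 at an unadjusted p under 0.05, and after the correction for GC content and length it called 2, with 4667. Leaving out libraries gave 0 to 8381: 0 without sham replicate 1, sham replicate 2 or BHB plus bIRI replicate 1 (unadjusted 5566, 5307 and 4676), 1 without BHB plus bIRI replicate 3, 794 without bIRI replicate 3, 1026 without sham replicate 3, 1154 without BHB plus bIRI replicate 2 and 8381 without bIRI replicate 1. Higher genes made up 36.03% of the calls, 43.85% with DESeq2 and 46.59% with all 9 tables.

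The injury genes called in the opposite direction with BHB, 895 with the 8 libraries, numbered 452 with a fold change of at least 2, 2339 with all 9 tables, 1508 with DESeq2, 2 after the GC and length correction and 0 with edgeR fitted to the compared groups only. Leaving out libraries gave 0 to 4529: 0 without sham replicate 1, sham replicate 2, BHB plus bIRI replicate 1 or BHB plus bIRI replicate 3, 281 without sham replicate 3, 388 without bIRI replicate 3, 475 without BHB plus bIRI replicate 2 and 4529 without bIRI replicate 1.

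With the replicate number as a block, edgeR called 0 genes in BHB plus bIRI against bIRI, 5270 had an unadjusted p under 0.05 (DESeq2 called 4210 without a block), and 0 injury genes moved back. The numbers do not show a pairing, since residuals of libraries with the same number had r from -0.206 to 0.0925 across genes.

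In bIRI against sham, 6303 genes were called with the 8 libraries, 4487 to 8433 under the alternatives that left out no library, and 4180 to 9064 without a library, the lowest without sham replicate 1 (4180) and sham replicate 2 (4192). In BHB plus bIRI against sham, 7826 were called, 5323 to 9984 under those alternatives and 5408 to 10308 without a library. Upper-quartile factors moved the median log2 fold change of all genes from 0.0848 to 0.17 in the former comparison and from 0.0362 to 0.133 in the latter.

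Camera called 24, 10 and 26 of 49 lists in the 3 comparisons. With an estimated correlation it called 1, 0 and 1. Fry called 26 lists in bIRI against sham, 0 in BHB plus bIRI against bIRI and 32 in BHB plus bIRI against sham. By camera with its preset correlation, leaving out libraries gave 5 to 18 lists in BHB plus bIRI against bIRI. There were 5 without bIRI replicate 3, 16 without BHB plus bIRI replicate 3 and 18 without bIRI replicate 1. It gave 23 to 28 lists in bIRI against sham and 25 to 28 in BHB plus bIRI against sham.

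For nuclear OXPHOS genes in bIRI against sham, the mean log2 fold change was -0.89, with a camera p of 0.172 with an estimated correlation. It ran from -0.99 to -0.64 under the alternatives and from -1.19 to -0.75 without a library. In BHB plus bIRI against bIRI the mean was 0.79, with a camera p of 0.115 with an estimated correlation. It was 0.16 after the GC and length correction (camera p 0.00194, preset correlation only), and 0.64 to 1.07 without a library. In BHB plus bIRI against sham, the mean was -0.11 and became -0.48 after that correction (camera p 1.26e-07, preset correlation only). Without a library it ran from -0.22 to 0.02, and it was above 0 without sham replicate 3 or without BHB plus bIRI replicate 2.

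Of 4255 values recomputed for 79 named genes, 3667 kept their direction and side of the threshold, 447 lost the threshold, 131 gained it and 10 reversed. All 10 reversed with 1 bIRI library left out, which leaves the other as the lone bIRI library, and ranges over the leave-outs of a library follow. In BHB plus bIRI against bIRI, log2 fold changes ran from the value without bIRI replicate 3 to that without bIRI replicate 1: Cdkn1a from -0.76 to 1.72, Il6 from -1.03 to 4.76, Krt20 from -1.63 to 2.53, Lcn2 from -0.58 to 0.77, Tnc from -0.81 to 1.94 and Vgf from -1.27 to 1.99. In bIRI against sham, Neat1 ran likewise from -0.033 to 4.06, Ppargc1a from -0.97 to 1.07 and Slc12a1 from -3.73 to 1.27, and Slc16a1 ran from -1.11 without bIRI replicate 1 to 1.17 without bIRI replicate 3.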

Other observations

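The tests chosen after the results were seen are those of bIRI replicate 3 as the whole source of the OXPHOS difference, of nuclear RNA in that library, of receptor genes on TMM-scaled library sizes, and of matched lists with other than 200 neighbours per gene.

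Immunoglobulin genes were uneven among the sham libraries. Ighm, the heavy chain gene of IgM, was at 10.9, 7.44 and 137 CPM in sham replicates 1, 2 and 3, Igkc at 9.02, 4.89 and 81.9 CPM, and Jchain at 4.001, 2.72 and 27.5 CPM. In bIRI against sham, edgeR gave log2 fold changes of -4.74, -4.03 and -4.04 with adjusted p of 0.0175, 0.0289 and 0.0215. Without sham replicate 3, Igkc was at -1.83 (edgeR adjusted p 0.0689) and Jchain at -2.28 (edgeR adjusted p 0.056).

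Nuclear OXPHOS genes were higher in BHB plus bIRI than in bIRI, and short transcripts were higher as a class. Without bIRI replicate 3 the mean log2 fold change was 0.64, so that this library alone did not set the direction, but edgeR called 3 of 79 genes, and the camera p of 4.72e-15 rests on the preset correlation, where the estimate with both bIRI libraries was 0.422 (p = 0.115). Among 10000 lists matched on length, GC content and expression, the OXPHOS median of 0.81 lay at percentile 97.96 with 200 neighbours per gene, the number tried first, past the bound set beforehand, which named no number of neighbours, but those neighbours were longer (median 1169 bases against 908). It lay at percentiles 67.76, 76.71, 89.14 and 99.77 with 25, 50, 100 and 400 neighbours, and with 25, the closest in length at 964 bases, at 99.97 against bIRI replicate 1 alone and 9.52 against replicate 3 alone, so that a difference shared by short transcripts cannot be told apart from one of OXPHOS genes. Both bIRI libraries, with the same label, also differed along transcript length, with Spearman's rho of 0.363 for replicate 3 minus replicate 1. For the BHB plus bIRI mean minus bIRI replicate 1, rho was -0.43 with length and 0.472 with GC content. The source of the length trend was not tested. An effect of BHB on mitochondrial genes is a candidate explanation that stays open, since BHB differs between the groups exactly as the libraries do.

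Apart from its group, bIRI replicate 3 differed from bIRI replicate 1 and the other libraries. Olfactory and vomeronasal receptor genes, read here as a gauge of genomic DNA, summed to 19.21 CPM of the total counts (95% interval 17.75 to 20.75) in bIRI replicate 3. They summed to 15.95 (14.75 to 17.21) in bIRI replicate 1 and at most 8.04 elsewhere. The intervals lay apart, which was the result set beforehand for genomic DNA. Of 120 receptor genes, 64 and 48 held counts in bIRI replicates 3 and 1. Transcription of some of them in kidney was not excluded, so that genomic DNA need not be the source of the sum. On TMM-scaled sizes, a scale added after the results were seen, replicates 3 and 1 were at 14.02 (12.96 to 15.15) and 14.38 CPM (13.30 to 15.52). The order of both bIRI libraries thus depended on the scale, while Neat1, at 1901 CPM against 106 in replicate 1, is too abundant for genomic DNA as the whole source. Sense-intronic and antisense genes, uncertain because the strand setting is unknown, had a median log2 ratio of 0.3625 between both bIRI libraries. It was above the 95th percentile of matched lists (0.2934) and below the level of 1 set for nuclear RNA. Long intergenic RNA genes were at 0.338, above their 95th percentile of 0.280. Genes of the GENCODE type TEC were at 0.298, below theirs of 0.311. Malat1 was at 597 and 104 CPM and Srrm2 at 418 and 68.5 CPM in bIRI replicates 3 and 1. For a larger share of medulla, collecting duct principal cell genes had a median log2 ratio of 0.8988, between the bounds set beforehand. Thick ascending limb genes were at 2.12, segment S3 genes at 0.885 and intercalated cell genes at 0.813. Distal convoluted and connecting tubule genes were at 0.534, and genes of segments S1 and S2 at 0.004. In mean log2 CPM, injury markers lay above sham by 2.82 in bIRI replicate 3 and 3.983 in bIRI replicate 1. Thick ascending limb genes lay at 0.090 and -1.73 from sham in bIRI replicates 3 and 1, and intercalated cell genes at -0.034 and -1.424. Genes of segments S1 and S2 went the other way, at -2.947 and -2.565. Nuclear RNA, the tissue piece, some genomic DNA and a difference in the extent of injury thus cannot be told apart with 1 such library. No biological explanation was tested, as both libraries carry the same label.

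For BHB plus bIRI against sham, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7826 genes, the highest of the others 0, and 1 of 10 splits gave as many as the real one.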
